A study of Cellvibrio japonicus with 12 samples.

How the data were processed

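Transcript levels were measured by Illumina sequencing of total RNA from wild-type Cellvibrio japonicus grown in a MOPS-buffered defined medium. Per the labels, metabolism was stopped with a mixture of ethanol and phenol, and 12 libraries were made: 3 for each of the 4 combinations of carbon source (glucose or cellobiose) and growth phase (exponential or stationary). Per the file headers, the authors deposited 1 mean RPKM (reads normalised for gene length and library size) for each group and each of 3812 features. A further table by the authors gives, per the file headers, a log2 fold change for the 2 carbon sources in exponential phase, with a value for 3786 features and none for 26. The aligner, the counting tool and its version, the genome build, the treatment of ribosomal RNA and the way replicates were averaged are not given in the sources used here. Values of single libraries were not analysed here, so no spread between cultures, standard error or p-value can be attached to any value, and the depth of the libraries is unknown.

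The analysis plan had foreseen a linear model for replicate values and, where only means were at hand, a comparison of sizes. The latter was used. Each mean RPKM was put on the scale log2(RPKM + 1), with a pseudocount of 1, and 2 groups were compared by the difference on that scale, which understates the change of low genes. Folds printed beside it are plain ratios of the authors' mean RPKM. A gene was counted when its mean reached an RPKM of 10 in at least 1 of the 4 groups, which held for 3768 features, and a difference was called large at 2-fold or more. The interaction of carbon source and growth phase was the difference between the stationary and the exponential carbon source differences. Means with no replicate error can place a large difference but cannot say whether it exceeds the spread between cultures. In simulated data made from these means, the 2-fold rule recovered 100% of 100 genes with a log2 change of 1.5 and 100% of 100 genes with a change of 2 in each of the 4 comparisons, over 3768 genes, with 0 unchanged genes called. That simulation assumed a noise of 0.1 (log2) on each mean, which the files cannot bear out, so it checks the arithmetic and not the error rate.

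Gene lists for functional groups were fixed by gene symbol before the data were examined, as were the comparisons, the 2-fold threshold, the alternatives not marked otherwise and the rule for named genes. That rule takes, in each comparison, the 8 genes with the largest difference in either direction among those with an RPKM of at least 10 in 1 of the 2 groups, all beta-glucosidase genes, and the highest and lowest members of each list (up to 2 of each for lists of 10 or more). The text prints a part of these, and that part was chosen after the values were seen, as were genes named outside the rule or carried into a comparison in which the rule did not take them. The list of transfer RNAs, the group of small and large ribosomal RNAs and the pooled list of carbohydrate enzymes were also added after the values were seen. Product names were not used, so lists hold only genes with a symbol, and the fixed list for cellobiose phosphorylases held 0 members. Each list's median was placed among 10000 random lists of the same size matched on mean expression in 10 bins. That percentile describes these means and is not a test, since genes of an operon are not independent.

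Features carry locus tags or symbols. In the RefSeq annotation ASM1922v1, 2357 features matched by locus tag, 561 by symbol and 4 by position, and 890 did not match. The assembly was used only for names, for the kind of RNA and for which genes neighbour each other, because the authors' build is not given in the sources used here. Unnamed genes are given by locus tag. Alternatives were pseudocounts of 0.1 and 5, no minimum RPKM or a minimum of 50, fold thresholds of 1.5 and 4, a shift of the median difference to 0, rescaling of all groups to the same sum and, chosen after seeing the data, the authors' deposited table and a beta-glucosidase list without bgl2A, bgl2B, bgl2C and bgl35A. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.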

Results

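Cellvibrio japonicus is a soil bacterium known for the breakdown of plant cell wall polysaccharides. Its transcripts were measured in cells fed glucose or cellobiose, the disaccharide of glucose released from cellulose, in exponential and in stationary phase. The 12 libraries fall into 4 groups of 3, and each value below is the authors' mean RPKM of a group, for which neither a standard deviation nor a depth can be given. The sum of the mean RPKM over all features was 1158664 in exponential glucose cells, 1238383 in exponential cellobiose cells, 1131773 in stationary glucose cells and 1197711 in stationary cellobiose cells. The most abundant feature in each group was ssrA, the transfer-messenger RNA that rescues stalled ribosomes. It took 6.68% of the sum in exponential glucose cells, 10.1% in exponential cellobiose cells, 10.8% in stationary glucose cells and 15.6% in stationary cellobiose cells. The 10 most abundant features took 14.3%, 17.3%, 18.9% and 30.4% in the same order. The 6 genes for the small and large ribosomal RNAs had a higher median in the second group of each comparison. Their copies share reads and are therefore uncertain individually. The difference was 1.35 (log2) for cellobiose over glucose in exponential phase and 1.26 in stationary phase. For stationary over exponential phase it was 1.38 in glucose and 1.29 in cellobiose. The 3 genes for 5S ribosomal RNA had medians of 0.34, 1.45, −0.20 and 1.02 in the same order. rrsA and rrlA stood at 328.5 and 319.4 RPKM in exponential glucose cells. Since the treatment of ribosomal RNA is not given, these values cannot be read as amounts of ribosomal RNA in the cells.

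The first comparison asks which transcripts differ between cellobiose and glucose during exponential growth. Of 127 genes in the carbohydrate enzyme lists 8 were at least 2-fold higher on cellobiose and 24 were below 0, with a median of 0.18 (log2), and a block of adjacent genes was also higher. The carbohydrate esterase gene ce2C had a mean RPKM of 97.7 on glucose and 1005 on cellobiose, 10.3-fold higher. Its preceding neighbours in locus-tag order, CJA_3100, CJA_3101 and CJA_3102, were 8.65-fold, 6.55-fold and 9.57-fold higher, CJA_3102 reaching 1502 RPKM. The endoglucanase gene cel5C was 5.10-fold higher (160.6 to 818.6 RPKM), the alpha-galactosidase gene aga27A 5.91-fold higher (40.3 to 238.0) and the alpha-xylosidase gene xyl31A 4.89-fold higher (170.5 to 833.9). CJA_0245 was 7.69-fold and CJA_3344 6.03-fold higher.

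Of the beta-glucosidase genes, whose products split cellobiose to glucose, cel3A was 2.85-fold higher on cellobiose, at 183.1 RPKM on glucose and 521.7 on cellobiose. The most abundant member, cel3B, was at 1424 and 1408 RPKM, a ratio of 0.989. cel3D was at 58.7 and 93.8 RPKM, and cel3C at 42.1 and 52.2. The list also held bgl35A, 4.11-fold higher, and bgl2A, bgl2B and bgl2C at log2 differences of 0.07, −0.34 and 0.28; their symbols carry the numbers of beta-galactosidase families. The median of the 8 genes was 0.29, the 99.7th percentile of matched random lists, and that of the cel3 genes alone was 0.49. Among the 10 mannan and galactan enzymes, 2 were at least 2-fold higher, aga27A and man26C (2.49-fold), and the median of 0.45 lay above that of all the random lists. The cellulase list held 29 genes, for cellulases and for carbohydrate-binding proteins (cbp symbols), not all of which bind cellulose. Of these, cel5C and cel9B (2.47-fold) passed 2-fold, while cbp35A and cel5B had log2 differences of −0.89 and −0.66. In the xylan and arabinan list 1 of 34 genes, xyl31A, passed 2-fold, and abfR was 1.94-fold higher. The lists were taken by symbol, so members such as abfR need not be enzymes. Of 19 starch and glycogen genes, amy13D was 2.34-fold higher. The pectin and chitin lists, of 17 and 10 genes, had none at 2-fold and medians of 0.22 and 0.14. All carbohydrate enzyme lists together held 127 genes, of which 8 were among the 54 genes at least 2-fold higher and 0 among the 17 at least 2-fold lower.

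The genes lower on cellobiose in exponential phase had no symbol. CJA_2519 was at 1156 RPKM on glucose and 280.1 on cellobiose, 4.13-fold lower. CJA_2520, CJA_2518, CJA_2517 and CJA_2514 were 4.05-fold, 3.75-fold, 3.09-fold and 2.96-fold lower, CJA_0283 2.74-fold and CJA_3602 2.47-fold. The transfer RNA gene CJA_3945 went from 10.3 to 2.73 RPKM, near the minimum. The type II secretion list, the export route of many degradative enzymes, had 12 of 13 members below 0 and a median of −0.25. The pilus list, of type IV genes with fimC and fimD of another kind of pilus, had a median of −0.16. Both lists lay at the 0.01 percentile, with 0 members past 2-fold. The 7 genes for phosphate uptake and its regulation were all above 0, with a median of 0.31. The 53 ribosomal proteins had a median of 0.09, and rpoS, for the general stress sigma factor, and rmf, for the ribosome modulation factor, had log2 differences of −0.58 and −0.50. Medians of the central carbon (0.05), nitrogen (0.04), amino acid (0.02), iron (0.04) and chaperone (0.03) lists turned negative when the median of all genes was shifted to 0, and those of the tricarboxylic acid cycle (−0.05), flagellum (−0.04), stress (−0.01) and sigma factor (0.00) lists were as small.

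Of 3768 counted genes, 54 were at least 2-fold higher and 17 at least 2-fold lower on cellobiose in exponential phase, 1.88% in all, and the middle of the distribution ran from −0.08 to 0.17 (quartiles). The authors' deposited table had 51 genes at least 2-fold higher and 22 lower, including 51 and 17 of the genes counted here. Across genes, the correlation between the log2 values of the authors' deposited table and the plain log2 ratio was 0.983. The values of the authors' deposited table lay closer to a ratio of quantile-normalised means (median absolute difference 0.0119) than to the plain ratio (0.0452), and its normalization is not given in the sources used here. No replicate check was possible for any of these differences.

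**Figure D1:**
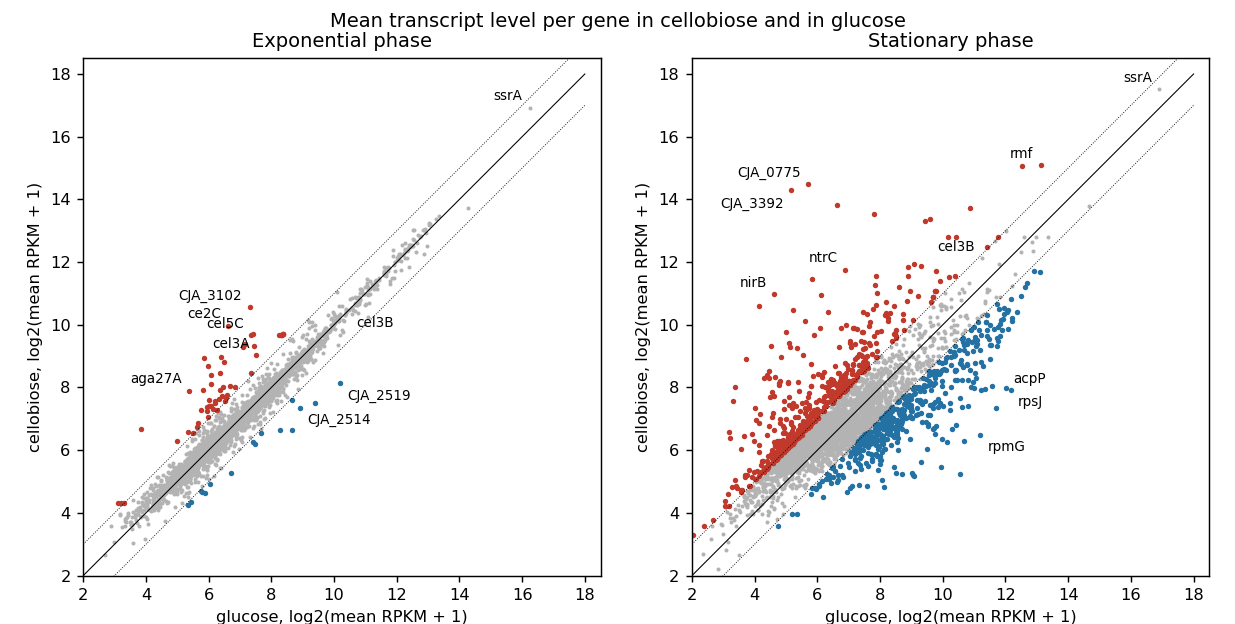
Each point is 1 gene, with its mean transcript level on glucose (x axis) and on cellobiose (y axis), both as log2(RPKM + 1), in exponential phase (left) and stationary phase (right). Red and blue points are at least 2-fold higher (54 left, 512 right) and lower (17 left, 454 right) on cellobiose, the solid line marks equal levels and the dotted lines mark 2-fold.

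The second comparison sets cellobiose against glucose in stationary phase. Most flagellar genes and 4 of 7 nitrogen assimilation genes were at least 2-fold higher on cellobiose, and most ribosomal protein genes were at least 2-fold lower. nirB and nirD, for the subunits of nitrite reductase, were at 23.5 and 36.6 RPKM on glucose and at 2014 and 1417 on cellobiose, 85.8-fold and 38.7-fold higher. Next to them, cobA, for a methyltransferase of the siroheme pathway, was 94.5-fold higher (16.5 to 1563 RPKM). ntrC, for the response regulator of nitrogen starvation, was 29.8-fold higher (116.1 to 3457 RPKM).

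The 3 largest differences were in unnamed genes, CJA_3392 (34.6 to 20359 RPKM, 589-fold), CJA_0775 (51.3 to 23186, 452-fold) and CJA_3391 (97.2 to 14514, 149-fold). CJA_1426 and CJA_1425 were 52.8-fold and 50.8-fold higher. Of the 7 members of the nitrogen list 4 were at least 2-fold higher, and the median of 2.86 lay above all random lists; the other members past 2-fold, named after their values were seen, were glnL (29.0-fold) and glnA, for glutamine synthetase (7.26-fold, to 13487 RPKM), and CJA_0528 (log2 3.13). glnA and glnL lie close together in locus-tag order (CJA_3534 and CJA_3536), so they need not count as independent members. glnD had a log2 difference of −0.999. Of 32 flagellar genes 21 were at least 2-fold higher, 0 were lower and the median was 1.78. Among them fliE was 8.99-fold and flgG 8.68-fold higher, while CJA_1703 and flhB differed by 0.18 and 0.25. Of 11 stress and ribosome hibernation genes 3 were at least 2-fold higher, rmf by 3.91-fold, csrA by 2.25-fold and rpoS by 2.17-fold, while bfr and CJA_2891 had log2 differences of −0.90 and −0.14; the median was 0.55. Of 15 chaperone and protease genes 2 were higher, clpA by 5.99-fold and lon by 2.41-fold, and 2 lower, groES by 2.77-fold and grpE by 2.29-fold.

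Ribosomal proteins were lower by at least 2-fold in 51 of 53 genes, with a median of −2.0. rpmG was 26.4-fold, rpmB 20.4-fold and rpsJ 19.1-fold lower on cellobiose, and the exceptions were rpsO (−0.18) and rpmJ (−0.83). efp, for elongation factor P, was 21.1-fold and acpP, for the acyl carrier protein of fatty acid synthesis, 16.3-fold lower. The transfer RNA genes CJA_3868, CJA_3915 and CJA_3914 were 40.2-fold, 22.5-fold and 15.5-fold lower. Of 46 transfer RNA genes 25 were at least 2-fold lower and 2 higher, which need not reflect mature transfer RNA. Of the 8 ATP synthase genes 6 were at least 2-fold lower (median −1.69, the 3.72 percentile of matched random lists), with atpE 4.63-fold lower. The tricarboxylic acid cycle list had 7 of 12 genes lower (median −1.06), sdhC by 8.11-fold, and the central carbon list 7 of 18 (median −0.68), with CJA_2671, one of the genes with the symbol tpiA, 9.54-fold and gnd 3.56-fold lower; these medians lay at the 35.1 and 47.8 percentiles of matched random lists. rpoD, for the housekeeping sigma factor, was 4.06-fold lower. Among the 77 genes of the amino acid list 19 were lower and 1, cysP, higher, with argG 6.06-fold lower. That list was taken by symbol. Beside biosynthesis genes it holds sulfate uptake genes such as cysP, regulators such as cysB and transfer RNA synthetases such as hisS.

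The genes cel3A, cel5C and ce2C were picked for a large difference in exponential phase, so a smaller one in stationary phase follows in part from that choice. cel3A was at 205.9 RPKM on glucose and 199.5 on cellobiose, cel5C at 198.3 and 208.0, and ce2C was 2.02-fold higher on cellobiose. cel3B was at 2443 and 4506 RPKM, 1.84-fold higher, and bgl2B passed 2-fold (2.45-fold). The beta-glucosidase median was 0.75, at the 91.5th percentile of the random lists. abfX was 6.06-fold and hex20B 3.02-fold higher, while cbp35A was 3.44-fold and cel5B 2.06-fold lower. The medians of the cellulase, xylan, mannan, pectin, chitin and starch lists ran from 0.64 to 0.75, from the 65.3 (starch) to the 95.5 percentile (mannan) of matched random lists. The medians of all counted genes in the lowest 2 sixths by glucose exponential level were 0.74 and 0.65. The 127 genes of all carbohydrate enzyme lists together had 17 higher and 2 lower and a median of 0.71, at the 99.9 percentile. Among all 3768 counted genes 512 were higher and 454 lower, so the share of higher genes was nearly the same. The share of lower genes was smaller in the lists, at 2 of 127 against 454 of 3768. The phosphate list had a median of 0.66 (85.0 percentile), and the single receptor gene cirA was 2.18-fold higher (81.2 percentile). The lists of chemotaxis, type II secretion, pilus and iron genes had medians of 0.42, −0.25, −0.02 and 0.01, the last turning negative with the median shifted to 0. These lay at the 94.6, 48.8, 79.2 and 45.6 percentiles of matched random lists.

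In all, 512 genes were at least 2-fold higher and 454 lower on cellobiose in stationary phase, 25.6% of those counted. The median difference of 0.20 moves the balance: 53% of the large differences were higher as scaled by the authors, 44.7% with all groups rescaled to the same sum and 33.9% with the median shifted to 0, where 312 genes were higher and 608 lower.

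**Figure D2:**
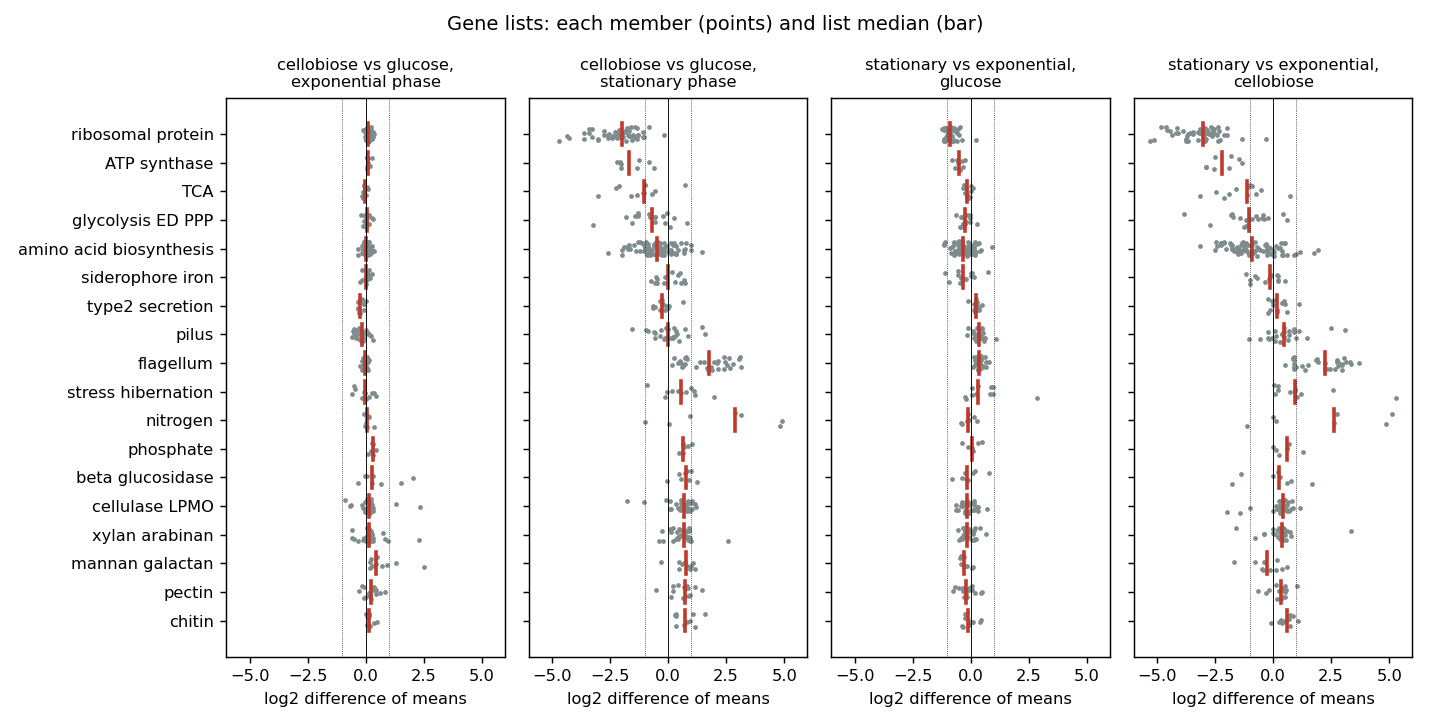
Each grey point is a gene of a functional list (y axis), placed by its log2 difference between the authors' group means (x axis) in 1 of the 4 comparisons, and each red bar is the list median; dotted lines mark 2-fold and vertical scatter has no meaning. Ribosomal protein medians are 0.09, −2.0, −0.90 and −3.0 and flagellum medians −0.04, 1.78, 0.36 and 2.22 from left to right.

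The third comparison follows glucose-grown cells from exponential to stationary phase. The most different genes were CJA_1305, CJA_1304 and CJA_1306, adjacent in locus-tag order. They went from 39.4 to 4585 RPKM (116-fold), from 74.9 to 7524 (101-fold) and from 57.8 to 5007 (86.6-fold), and CJA_1303 beside them was 8.41-fold higher. CJA_1305 had no match in the RefSeq annotation, where little room lies between CJA_1304 and CJA_1306. Its value may therefore not be separate from theirs. zigA, for a metal-binding GTPase linked to zinc supply, was 54.4-fold higher (50.5 to 2749 RPKM), and its neighbour CJA_3464 was 7.79-fold higher. rmf was 7.16-fold higher in stationary phase (1243 to 8894 RPKM), and CJA_2390 was 5.54-fold higher.

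Ribosomal proteins were lower in stationary glucose cells, by at least 2-fold in 17 of 53 genes, with a median of −0.90 and with rplL and rplJ 2.33-fold and 2.24-fold lower. Of the 46 transfer RNA genes 11 were at least 2-fold lower. The amino acid list had 3 of 77 genes lower and a median of −0.32, with metF 2.24-fold and metK 2.23-fold lower, and the iron list had exbB 2.16-fold lower. CJA_3403 was 4.32-fold lower (244.6 to 56.6 RPKM), CJA_0499 3.34-fold, and the neighbours CJA_0878 and CJA_0877 were 3.19-fold and 3.11-fold lower. CJA_0893, CJA_3058 and CJA_3862 were 3.08-fold, 3.00-fold and 2.66-fold lower, and CJA_3945 again lay near the minimum, at 10.3 and 3.07 RPKM. Flagellar genes were above 0 in 32 of 32 cases with a median of 0.36 and 0 past 2-fold, and the pilus median was also 0.36 with 1 gene, CJA_2401, past 2-fold. Among the sigma factors rpoH, for the heat shock sigma factor, was 2.09-fold higher.

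The nitrogen list had a median of −0.10 and 0 genes past 2-fold in glucose. ATP synthase, tricarboxylic acid cycle and central carbon genes had medians of −0.50, −0.16 and −0.25 with 0 genes past 2-fold. None of the 8 beta-glucosidase genes passed 2-fold; cel3B was at 1424 and 2443 RPKM and cel3A at 183.1 and 205.9. Their median was −0.16, or 0.13 for the cel3 genes alone. In all, 97 genes were at least 2-fold higher and 76 lower, 4.59% of those counted. Of these, 56.1% were higher as scaled by the authors and 68.5% with the median shifted to 0.

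The fourth comparison follows cellobiose-grown cells from exponential to stationary phase, where more genes differed than in glucose. CJA_3392, CJA_0775 and CJA_3391 were 433-fold, 284-fold and 152-fold higher in stationary phase, CJA_1425 113-fold and CJA_1426 106-fold. phoH was 69.3-fold higher (145.6 to 10097 RPKM), CJA_1304 68.7-fold (75.8 to 5208) and CJA_1388 62.4-fold (171.0 to 10667). rmf was 39.5-fold higher (879.2 to 34770 RPKM) and rpoS 5.97-fold (192.4 to 1149). ntrC was 35.4-fold higher (97.6 to 3457 RPKM), and the nitrogen list had 4 of 7 genes higher and 1, glnD, lower by 2.18-fold, with a median of 2.62.

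Ribosomal proteins were at least 2-fold lower in 52 of 53 genes, with a median of −3.0. rpmG went from 3577 to 89.2 RPKM and rpsJ from 8404 to 242.1, 40.1-fold and 34.7-fold lower, while rpsO was at 6294 and 5104. acpP was 33.4-fold and efp 31.5-fold lower. The transfer RNA genes CJA_3868, CJA_3915, CJA_3914 and CJA_3916 were 69.8-fold, 41.7-fold, 31.6-fold and 29.6-fold lower. Of 46 transfer RNA genes 36 were at least 2-fold lower and 1 was higher. CJA_3868 lay in a run of 13 lower neighbours from CJA_3865 to rpoB, which also held ribosomal protein genes. Group means cannot tell mature transfer RNA from its precursors or from reads of neighbouring transcripts. ATP synthase genes were lower in 8 of 8 cases (median −2.20), atpB by 7.55-fold. The tricarboxylic acid cycle had 7 of 12 genes lower, sdhC by 8.92-fold, and central carbon metabolism 9 of 18, CJA_2671 by 14.4-fold and gnd by 6.61-fold, with medians at the 33.8 and 17.5 percentiles of matched random lists. Of the 77 genes of the amino acid list 36 were lower and 4 higher. argG was 8.96-fold and cysI 5.69-fold lower. The higher ones included cysP (3.82-fold), of sulfate uptake, and cysB (3.43-fold), for a regulator.

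Flagellar genes were at least 2-fold higher in 23 of 32 cases, with a median of 2.22; flgG went from 156.4 to 2069 RPKM and fliE from 91.1 to 951.1. Of the 5 chemotaxis genes 4 were higher, cheZ by 3.35-fold, and of 25 pilus genes 4 were higher and 1 lower, pilH by 5.68-fold and pilF by 2.06-fold in turn. Of 15 chaperone and protease genes 5 were higher, clpA by 13.0-fold and lon by 2.83-fold, and 4 lower, groES by 3.76-fold. rpoD was 5.05-fold lower. Of the 8 enzyme genes at least 2-fold higher on cellobiose in exponential phase 6 were at least 2-fold lower in stationary phase, among them cel5C by 3.94-fold, bgl35A by 3.46-fold, aga27A by 3.24-fold, xyl31A by 3.03-fold and cel3A by 2.62-fold. These genes were picked by the exponential cellobiose mean that this comparison also uses, which favours lower values in stationary phase by an amount that group means cannot give. The other 2, cel9B and man26C, had log2 differences of −0.99 and −0.45, and cel3B was 3.20-fold higher. The beta-glucosidase median was 0.27. abfX was 10.4-fold, glgC_2191507 6.10-fold and mal77Q 5.26-fold higher. The medians of the cellulase, xylan, pectin, chitin and starch lists were 0.40, 0.37, 0.34, 0.59 and 0.28, between the 33.3 (starch) and 92.8 (chitin) percentiles of matched random lists, and that of the mannan list was −0.27, at the 0.81 percentile. In all, 531 genes were at least 2-fold higher and 598 lower, 29.96% of those counted, with a median of 0.14 over all genes. With the median shifted to 0 the counts were 439 and 704, 38.4% rather than 47.0% higher.

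**Figure D3:**
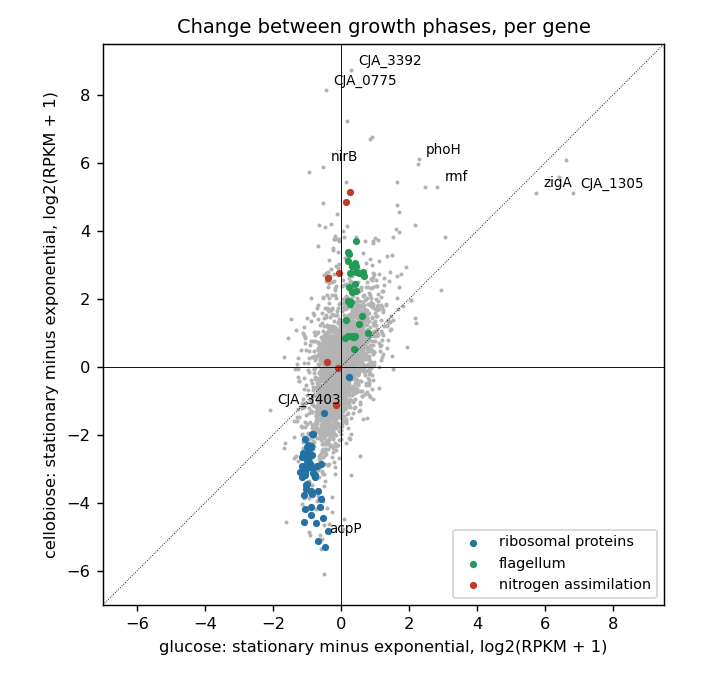
Each point is 1 gene, placed by its difference between stationary and exponential phase in glucose (x axis) and in cellobiose (y axis), both as log2(RPKM + 1); the dotted line marks equal differences. Ribosomal proteins (medians −0.90 and −3.0), flagellar genes (0.36 and 2.22) and nitrogen assimilation genes (−0.10 and 2.62) spread along the cellobiose axis, while CJA_1305 and zigA are far from 0 on both axes.

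The carbon source and growth phase comparisons were also set against each other. Between the phases, 79 of the 97 genes higher in glucose were also higher in cellobiose (13.7 for independent lists), and 51 of the 76 lower genes were also lower (12.1 for independent lists). CJA_1304, zigA and rmf were among the shared higher genes, and the last was further apart in cellobiose. Of the 54 genes higher on cellobiose in exponential phase 19 were higher in stationary phase too (7.34 for independent lists), among them CJA_3102, CJA_3100 and CJA_3101. Of the 17 lower genes 9 were lower in both phases (2.05 for independent lists), CJA_2519 and CJA_2514 among them, and 5 were at least 2-fold higher in stationary phase. The libraries compared within each pair are separate. The carbon source difference was not the same in both phases, by at least 2-fold, for 910 genes (24.2%), upwards in 446 and downwards in 464, and 37.4% rather than 49.0% of these were upwards with the median shifted to 0. For CJA_0775, CJA_3392, nirB and ntrC it was larger in stationary phase by 8.57, 8.43, 6.41 and 4.87 (log2), and for ce2C, cel5C and cel3A it was smaller, at −2.34, −2.27 and −1.55; these genes were picked for a large difference in 1 phase.

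**Figure D4:**
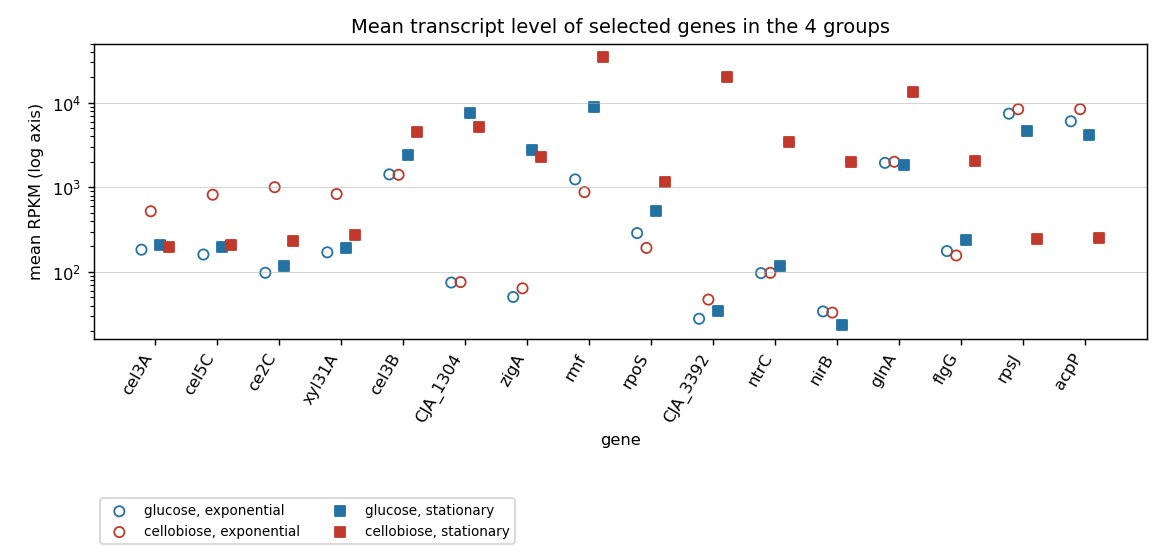
Mean RPKM (log axis) of 16 genes (x axis) in the 4 groups; open circles are exponential and filled squares stationary phase, blue is glucose and red is cellobiose, and each symbol is the authors' mean with no error available. The circles for cel3A, cel5C, ce2C and xyl31A separate by carbon source, while for ntrC and nirB the stationary cellobiose value (3457 and 2014 RPKM) stands apart from the other groups.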

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

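The fold threshold moved the counts of large differences most. At 1.5-fold the counts of higher and lower genes were 131 and 68 for carbon source in exponential phase, 1186 and 791 in stationary phase, 327 and 323 between phases in glucose and 972 and 930 in cellobiose. At 4-fold they were 16 and 2, 115 and 105, 15 and 1, and 174 and 193, since a stricter threshold admits fewer genes. With the median shifted to 0, 312 genes were higher on cellobiose in stationary phase in place of 512. The other 55 of 72 recomputed counts stayed within 1.5 times the value reported, and these include pseudocounts of 0.1 and 5, no minimum RPKM, a minimum of 50, the same sum for all groups and, added after seeing the data, the authors' deposited table. No list median moved by more than 1.5-fold in 388 recomputations with other pseudocounts, minimum values or members, and the largest move was 0.45 (log2). Many list medians are themselves smaller than 1.5-fold, so this bound is loose and would not catch a change of sign. The shift of the median moves all genes of a comparison alike, by at most 0.20. It could not move a median by 1.5-fold, but 8 medians between −0.06 and 0.08 changed sign with the median shifted to 0. The beta-glucosidase median between phases in glucose went from −0.16 to 0.13 without bgl2A, bgl2B, bgl2C and bgl35A. Of 806 values of named genes recomputed without that shift 1 moved by more than 1.5-fold, CJA_3945 in exponential phase, from −1.60 to −0.98 with a pseudocount of 5. No paired analysis was possible because the values are group means that carry no replicate numbers, and leaving out single replicates and thresholds on adjusted p-values were not run for the same reason. Lists by symbol alone were not run separately, since the lists already rest on symbols. With depth and replicate spread unknown, genes near the minimum RPKM are the least certain.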

Other observations

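Tests chosen after the result was seen were those of a uniform background and of ribosomal and transfer RNA loss, the count of neighbouring pairs and the nitrogen-source medians without some genes. The tests of nitrogen-source genes and of sampling time were set before their values were seen, but after the values of related genes and the correlation between the phase differences. The genes in the next paragraph were also chosen after their values were seen.

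Large differences ran in blocks of adjacent genes. In stationary phase, 13 neighbours from CJA_0541 to CJA_0553 were each at least 2-fold higher on cellobiose, by 1.31 to 5.19 (log2). They include xdhA, xdhB and xdhC, for xanthine dehydrogenase, at 39.3-fold, 17.0-fold and 9.83-fold, and uraD, uraH and guaD of purine breakdown at 8.18-fold, 6.37-fold and 5.34-fold. A second block of 13, CJA_0563 to CJA_0576, was higher by 1.03 to 4.33, and 12 genes from CJA_3041 to CJA_3052 by 1.05 to 1.51. Lower blocks were as long or longer, with 25 genes from rpsL to rplO and 12 from CJA_3865 to rplL. Both of these hold ribosomal protein genes. gdhA, for glutamate dehydrogenase, went from 711.0 RPKM in exponential to 176.2 in stationary phase in cellobiose. Between the carbon sources in stationary phase 293 adjacent pairs differed at least 2-fold in the same direction, against a mean of 79.5 and a highest value of 116 in 10000 shuffles of the gene order, and in exponential phase 13 did, against 0.317 and 4.

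Of 7 nitrogen assimilation genes 4 (ntrC, glnL, glnA and CJA_0528) were at least 2-fold higher in stationary cellobiose cells than in each of the other 3 groups, while glnD was lowest there (81.0 RPKM) and glnE was at 102.5 RPKM. Nitrogen depletion in those cultures may account for it. For the test, 10 of 21 listed nitrogen-source symbols matched 13 genes. The other symbols, among them amtB, glnK, nasA and ureA to ureG, matched no counted gene by symbol, so the test does not cover them. The median of the 13 genes was 0.83 between the phases in cellobiose and −0.30 in glucose. The cellobiose value lay short of the 1 set for depletion and above the 0.5 set against it. The median of 0.83 lay at the 99.8 percentile of matched random lists, with medians of 0.43 and 0.40 for all genes in the lowest 2 sixths by level. Adjacent genes had already been seen to be higher for 6 of the 13; the median was 0.74 without uraH and guaD and 0.39, at the 61.2 percentile and below the 0.5 set against depletion, without CJA_1237 to CJA_1240 as well. Of those 7 genes, CJA_0957 closes a run from CJA_0953 that was higher on cellobiose in stationary phase, by 1.01 to 1.30. The 7 genes spread from 0.18 to 1.04. Both bounds were set for the median of the whole set, which lay between them, while the smaller sets were chosen afterwards. The outcome depends on which genes are kept, so the test does not decide on depletion. An effect of the sugar itself was not tested.

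In stationary cellobiose cells, genes of low exponential level were higher and genes of high level lower: the median differences by sixth of glucose exponential level were 0.43, 0.40, 0.26, −0.02, −0.37 and −1.26. Loss of ribosomal protein and transfer RNA transcripts alone is argued against by the highest sixth without these and other non-coding RNA, which still had a median of −1.06. A uniform background of reads, such as genomic DNA, was first tested by the share of the lowest sixth below the RPKM it had gained, 1.75% (11 of 628 genes below 11.3 RPKM), which met the prediction for a background; that test was set aside because exponential cellobiose cells gave 1.91%, and the next was chosen after the gains by level had been seen. A background adds equal RPKM to each gene, but the lowest 157 genes gained a median of 4.63 RPKM, with an upper quartile of 11.9, against a median of 14.3 in the highest 157 of the same sixth. A nonuniform background and a real redistribution of transcripts may both remain, and no biological explanation was tested.

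More genes differed between the phases in cellobiose than in glucose. The glucose cultures may have been sampled at an earlier point of the same course. Of 173 genes at least 2-fold different in glucose, 154 (89.0%) went the same way in cellobiose, just under the 90% set for this explanation and against 64.8% of all counted genes (correlation across genes 0.528), and 59.0% went further the same way, between the bounds of 80% and 50%. The 173 genes were picked for a large difference in glucose, which favours a smaller one in cellobiose by an amount that group means cannot give. Genes that differed in cellobiose alone were not part of this test. The 2 sugars and the sampling time cannot be told apart here, since the time of sampling is not given in the sources used here and each group has 1 time point.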
